A study of Mus musculus with 9 samples.

How the data were processed

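Newborn offspring of heterozygous Alox12b knockout parents were genotyped, and trunk epidermis was lifted off the dermis after a short bath in hot buffered saline, per the labels' protocols. Biotin-labelled cRNA was made from total RNA with a kit that primes at the 3′ end of transcripts and was hybridised to Affymetrix Mouse Genome U430 2.0 arrays, per the labels' protocols. Probe sets of such arrays read mostly the 3′ end of a transcript.

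The authors deposited 1 table of log2 expression values with 45037 probe sets for 9 arrays. The affy package is named in the submitters' processing notes, without a version. The background correction, the normalization and the summary of probes into probe sets are not given in the sources used here. The log2 scale was read from the values, which ran from 1.43 to 14.46, and array medians differed by less than 0.5, so the values were used as deposited. The table used here held 0 Affymetrix control probe sets, so the planned check of 3′ against 5′ control signals was not run. Arrays carry no read depth, and their number limits the precision.

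Groups and replicate numbers came from the sample titles. The groups share all replicate numbers but 5, and a fit with the replicate number as a block was made as an alternative. Number 5 is in wildtype only, so the block takes that array out of the comparison. Values were identical for at most 124 of 45037 probe sets between any 2 arrays of a group, so no array was a copy of another.

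Probe sets were named through the platform annotation, with 34945 naming 1 gene, 932 naming several and 9160 not listed. Of the first, 34741 matched the GRCm38.p6 gene table by gene number and 204 did not. That table was used for names and neighbouring genes only, and no coordinates are given because the build behind the annotation is not given in the sources used here. The probe set with the highest mean over all arrays stood for its gene, which left 18193 genes, 9010 of them with several probe sets. No gene had probe sets past the threshold in both directions. Of 132 called genes with several probe sets, the next brightest had the same sign in 104.

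Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, no filter on dim probe sets) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Differences are knockout minus wildtype on the log2 scale. Gene lists for epidermal biology and for other cell types, 38 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. List medians were also set against 10000 random lists matched on mean expression, and intervals of list medians came from 10000 bootstrap draws of the list's genes. Shares of called genes were compared with Fisher's exact test, and array measures with exact permutation tests over all 126 splits of 9 arrays into 4 and 5.

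Named genes followed a rule set before the data were examined. It took Alox12b, the 12 largest differences in each direction among called genes whose groups did not overlap, up to 3 members higher and 3 lower per list, 2 members as values for lists with none called, and called genes near Alox12b. Provisional gene symbols were left out of the 12.

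The code was tested on simulated data made from the real means and spreads of all 18193 genes for the knockout and wildtype comparison, with 200 genes changed. It recovered 78% of genes changed by 1 on the log2 scale and 90% of genes changed by 2. It called 12 unchanged genes.

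Alternatives were other summaries of probe sets, a filter on level, quantile normalization, median centring, eBayes with trend and robust settings, array weights, a residual principal component or the Xist level as covariate, the replicate block, other thresholds and windows, and each array left out in turn. Leaving out X and Y genes, or wildtype arrays 3 and 5 together, was added after the data had been seen.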

Results

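Gene expression was measured in the trunk epidermis of newborn mice labelled as knockout for Alox12b, the 12R-lipoxygenase that oxidises the linoleate of epidermal acylceramides, and of mice labelled wildtype. Ichthyosis and a leaking skin barrier follow from loss of this enzyme. The series held 9 Affymetrix Mouse Genome U430 2.0 arrays, 4 labelled knockout and 5 labelled wildtype, and the labels call the samples of each group biological replicates. Each array had 45037 probe sets on a log2 scale, with array medians between 3.14 and 3.31. The number of arrays limits the precision of every value given here.

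Alox12b itself did not separate the groups. Its only probe set, 1418266_at, read 11.13 ± 0.33 (SD, n = 4) on the knockout arrays and 10.91 ± 0.29 (SD, n = 5) on the wildtype arrays, a log2 difference of 0.23 with a limma adjusted p of 0.547. The labels do not say which part of the gene was deleted and the position of the probes was not used here, so this value checks nothing about the labels. The groups are therefore named below as the arrays are labelled.

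Sex-linked genes moved with the groups. Xist, the RNA that coats the inactive X chromosome, read 10.12 ± 0.09 (SD, n = 4) on the knockout arrays. It read 10.95 on wildtype array 4 and between 3.23 and 4.32 on the other wildtype arrays. The Y-linked gene Eif2s3y read between 2.00 and 2.43 on the knockout arrays, 2.11 on wildtype array 4 and between 7.67 and 8.04 on the other wildtype arrays. All 4 knockout samples and 1 of 5 wildtype samples thus had the female pattern, and genotype and sex overlapped almost completely. Of the genes called below, 8 lay on the X chromosome, where 617 genes were tested.

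The comparison asked which transcripts differ in newborn epidermis between the samples labelled knockout and wildtype. Tnfaip3, an inhibitor of NF-kB signalling, rose 18.3-fold, from 4.46 ± 0.38 (SD, n = 5) to 8.66 ± 1.79 (SD, n = 4) on the log2 scale, with a limma adjusted p of 0.0160. Hbegf rose 10.7-fold and Epgn 9.61-fold, and both encode ligands of the EGF receptor. Phlda1 rose 10.1-fold. The transcription factor genes Nr4a1, Fosb, Atf3 and Egr1 rose 8.52-fold, 7.85-fold, 5.92-fold and 4.95-fold. Ccn1, a secreted matricellular protein gene, rose 6.68-fold, Arc 6.29-fold, the sialidase gene Neu2 6.22-fold and Sprr2h 4.83-fold. The knockout values of Tnfaip3 ran from 6.64 on array 3 to 10.34 on array 1, so its size varied widely within the group. Epgn read 4.70 on knockout array 3 and 6.84 to 7.90 on the other knockout arrays. Without knockout array 3 the rise was 29.2-fold for Tnfaip3, 15.6-fold for Epgn and 10.1-fold for Ccn1. With the mean of a gene's probe sets it was 6.04-fold for Tnfaip3, and Ccn1 did not pass, at 4.17-fold and a limma adjusted p of 0.0579, nor at 3.12-fold without the less specific probe sets (limma adjusted p of 0.147). The only probe set of Sprr2h was also of the less specific kind.

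Among the genes named by the rule, the largest falls were in transcripts of other kinds. Neat1, the long noncoding RNA of paraspeckles, fell by 3.15 on the log2 scale, from 10.81 ± 0.32 (SD, n = 5) to 7.66 ± 0.97 (SD, n = 4), with a limma adjusted p of 0.00393. Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 2.89. Rsrp1 fell by 2.29, and the zinc finger genes Rbak, Zfp799, Zfp160 and Zfp707 fell by 2.12, 1.96, 1.79 and 1.77. The calcium pump gene Atp2b4 fell by 1.99 and Far2, a fatty acyl-CoA reductase gene of wax ester synthesis, fell by 1.81. Pdcd7 fell by 1.76, Axin2, a target and inhibitor of Wnt signalling, by 1.76, and Clca3a2 by 1.71. Axin2 and Zfp160 each had a dimmer probe set that differed by 0.16 and 0.03, not past the threshold, and with the mean of a gene's probe sets they fell by 0.80 and 0.88. Neat1 then fell by 1.72 and Rsrp1 by 1.47, while Far2, at -1.15, and Clca3a2, at -1.67, did not pass, with limma adjusted p values of 0.0506 and 0.0777.

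Several of these genes were dim in the group with the lower level. Where Xist was low it read 3.23 to 4.32, and 8 of the 24 genes above had a lower group mean under 4.32, a mark chosen after the values were seen. The wildtype mean was 3.54 for Epgn and 3.54 for Arc, and the knockout mean was 2.78 for Zfp799, 3.16 for Pdcd7, 3.28 for Zfp160, 3.46 for Zfp707, 3.97 for Rbak and 4.16 for Axin2. Background differs between probe sets and detection calls were not used here, so these levels may not lie above background and the folds and differences of these genes are those of the deposited values, which can understate a change. The same held for 13 of 93 genes called higher and 40 of 133 called lower, among them Irf9 at 3.92 in knockout.

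**Figure D1:**
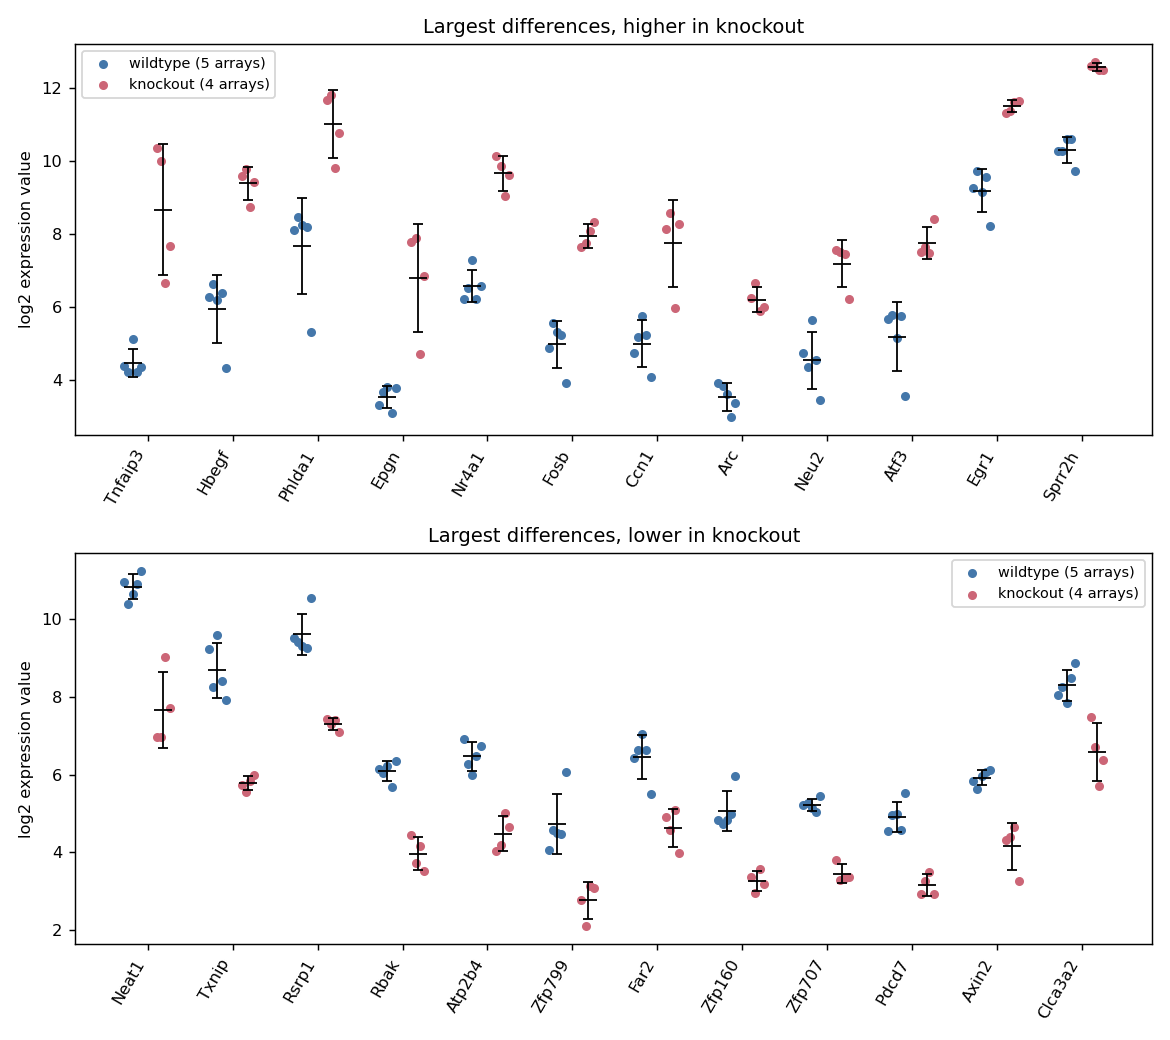
Log2 expression values of the 12 genes named by the rule for the largest differences in each direction, for 5 wildtype and 4 knockout arrays. Points are arrays, horizontal marks are group means and bars are 1 SD. In each of these genes the groups do not overlap, with Tnfaip3 differing by 4.20 and Neat1 by -3.15.

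In total 226 of 18193 genes passed an adjusted p of 0.05 in limma, 93 higher and 133 lower in knockout, and 126 of them differed at least 2-fold, 58 higher and 68 lower. The groups did not overlap for 1506 genes, or 8.28%, where chance gives 1.59%. With quantile normalization the split was 147 higher and 143 lower, and with a residual principal component it was 326 higher and 1128 lower. That component was taken from the same values after removal of the group means. It leaves every difference as it was and lowers only the spread. With the Xist level as a covariate 9 genes passed, 8 higher and 1 lower. The higher ones were Arc, Nr4a1, Junb, Zfp36, Btg2, Dusp1, Sprr2h and Cdr2 and the lower one was Zfp707, named after their values were seen. The median size of the 226 differences was then 1.00 against 1.08, and their median SE was 0.28 against 0.18. The total was 62 without knockout array 2, 71 without wildtype array 2, 83 without wildtype array 1, 87 without knockout array 4 and 89 without wildtype array 4. The number with at least 2-fold differences was 57, 57, 64, 61 and 71 without the same arrays. The direction in which more genes passed depended on single arrays. Without knockout array 3 it was 127 higher and 94 lower, of which 87 and 55 differed at least 2-fold, and without knockout array 4 it was 48 higher and 39 lower, of which 33 and 28 did. Without knockout array 1 it was 63 higher and 181 lower, of which 45 and 101 did. Of the 34 named genes that passed, 15 still passed without knockout array 2, 18 without wildtype array 2, 20 without wildtype array 1, 18 without knockout array 4, 19 without wildtype array 4 and 4 with the Xist covariate.

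Among the gene lists fixed before the data were examined, the small proline-rich genes, which encode cross-linked proteins of the cornified envelope, stood highest. Of 9 measured members 3 rose over all genes tested and 8 rose when adjusted over the list alone. Sprr2h rose by 2.27, Sprr2d by 2.26 and Sprr2k by 0.81, and the list median was 2.27. The list mean was 7.12 on knockout array 3, within the wildtype range of 5.69 to 7.64, and between 9.04 and 9.98 on the other knockout arrays. The camera adjusted p was 1.09e-07, and the adjusted p was 0.801 with an estimated correlation. Of 15 late cornified envelope genes 1 rose, also 1 when adjusted over the list alone. This was Lce3c, by 2.10, while 3 of the 15 differences were positive and the list median was -0.52, with a camera adjusted p of 0.0781. Sprr2h and Lce3c each had 1 probe set, of the less specific kind. Of 23 other cornified envelope precursors 0 passed in limma, 8 had an unadjusted p under 0.05 and 5 passed when adjusted over the list alone. Rptn read 10.70 against 9.30 and Tchhl1 4.73 against 5.75.

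The acylceramide and lipid envelope list, in which Alox12b acts, was higher as a list by camera, with a median of 0.22 and an adjusted p of 0.00936. The adjusted p was 0.801 with an estimated correlation. None of its 23 members passed in limma, 7 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. Degs2 read 8.69 against 7.79, and the retinol dehydrogenase family gene Sdr9c7 read 8.94 against 8.33. The list of fatty acid oxidation and PPAR targets was lower, with a median of -0.30, a camera adjusted p of 0.00582 and an adjusted p of 0.801 with an estimated correlation. None of its 22 members passed in limma, 9 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Its largest differences were in Cd36, at 4.38 against 6.11, and in Fabp4, at 7.42 against 8.94, and Fabp4 also belongs to the adipocyte list. The list mean was 7.22 on wildtype array 3 and 6.53 on wildtype array 1, within the knockout range of 6.37 to 6.64. Among the wildtype arrays the adipocyte list was also highest on array 3 and lowest on array 1. Sterol synthesis had a median of 0.21 and a camera adjusted p of 0.0737, and fatty acid synthesis a median of 0.04 with a mean of -0.03 and a camera adjusted p of 0.651. The lipoxygenase and eicosanoid list had a median of 0.07 and a camera adjusted p of 0.599, with Ptgs2 at 3.12 against 2.17.

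The EGF receptor ligands were higher, with 2 of 7 members risen, 3 when adjusted over the list alone, a camera adjusted p of 0.0348 and an adjusted p of 0.801 with an estimated correlation. Hbegf and Epgn were the members that rose. The list median was 0.15, at percentile 92.4 of expression-matched random lists, and the list mean was 1.33. The camera result thus rests mainly on a few members. Epidermal cytokines and chemokines were higher, with a median of 0.26, a camera adjusted p of 0.000465 and an adjusted p of 0.581 with an estimated correlation. None of 24 members passed in limma, 8 had an unadjusted p under 0.05 and 4 passed when adjusted over the list alone. Ccl20 read 7.51 ± 2.25 (SD, n = 4) against 3.72 ± 0.18 (SD, n = 5), with values of 9.73 and 9.17 on knockout arrays 1 and 2. The unfolded protein response list was higher, with 2 of 20 members risen, 2 when adjusted over the list alone, a camera adjusted p of 0.0382 and an adjusted p of 0.801 with an estimated correlation. Its risen members were Atf3, which many other stresses also induce, and Chac1, a glutathione-degrading enzyme gene, by 0.91. Epidermal proteases and inhibitors were higher, with 1 of 28 members risen, 2 when adjusted over the list alone, a camera adjusted p of 0.0382 and an adjusted p of 0.801 with an estimated correlation. The member that rose was Klk6, by 1.72. The list median was 0.18, and the list means of the groups overlapped, at 9.33 to 9.59 in knockout and 8.97 to 9.57 in wildtype. Among stress keratins and alarmins 1 of 11 fell, Hmgb2 by 0.57, while the list median was 0.54 with a camera adjusted p of 0.0781. With the mean of a gene's probe sets Hmgb2 did not pass, at -0.39 and a limma adjusted p of 0.0648. When adjusted over the list alone, 4 of the 11 rose and 1 fell.

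Basal keratinocyte genes were lower as a list, with a median of -0.40, a camera adjusted p of 0.0246 and an adjusted p of 0.801 with an estimated correlation. None of 14 passed in limma, 7 had an unadjusted p under 0.05 and 4 were lower when adjusted over the list alone. Trp63 read 6.12 against 7.54 and Dst 6.57 against 7.75. Without knockout array 3 the list median was -0.24. Spinous and granular keratins had a median of -0.07 and a camera adjusted p of 0.385, desmosomes -0.21 and 0.246, and tight junctions -0.20 and 0.219. The cell cycle list had a median of -0.07 and a camera adjusted p of 0.776, antimicrobial proteins 0.15 and 0.436, NRF2 targets -0.06 and 0.385, and hypoxia and glycolysis 0.18 and 0.0701. In the interferon-stimulated list Irf9 fell by 0.82, the 1 member also past when adjusted over the list alone, with a list median of 0.04, a mean of -0.03 and a camera adjusted p of 0.916. In the epidermal transcription factor list Cebpb rose by 0.65, likewise 1 when adjusted over the list alone, with a list median of 0.03 and a camera adjusted p of 0.651.

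**Figure D2:**
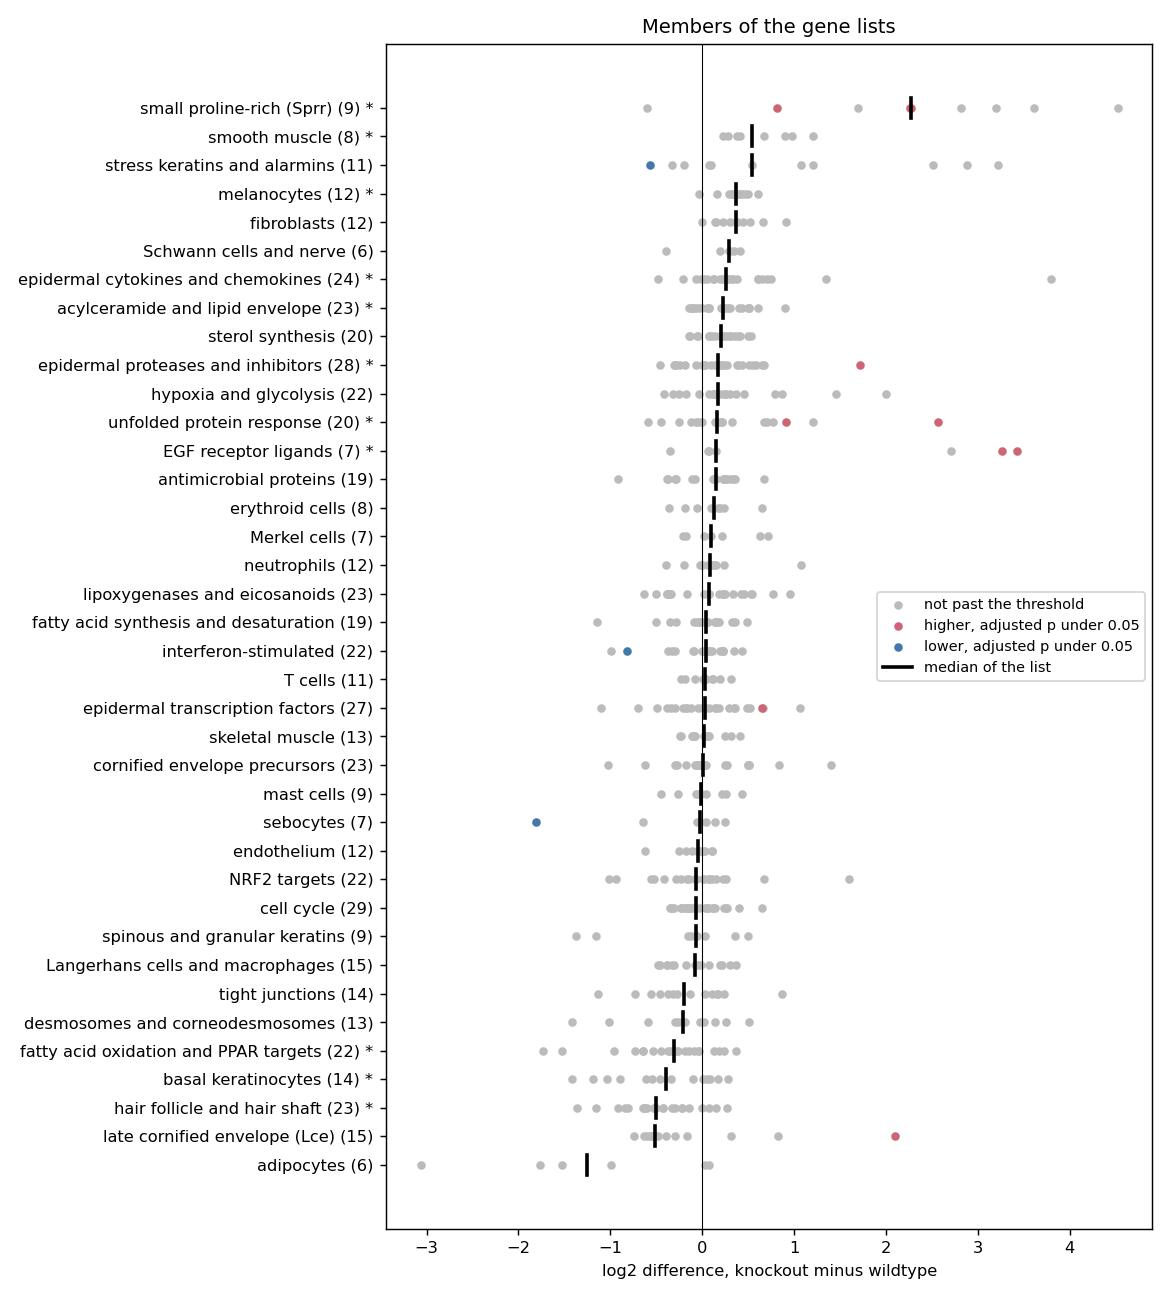
Log2 differences, knockout minus wildtype, of the measured members of 38 gene lists, with the number of members in brackets. Points are genes, thick marks are list medians and an asterisk marks a camera adjusted p under 0.05, as in 11 lists. The small proline-rich list has a median of 2.27 and the adipocyte list one of -1.25.

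Hair follicle and hair shaft markers were lower as a list, with a median of -0.50, a camera adjusted p of 0.00109 and an adjusted p of 0.801 with an estimated correlation. None of 23 passed in limma, 6 had an unadjusted p under 0.05 and 2 were lower when adjusted over the list alone. Tchh read 8.30 against 9.66 and Krt27 7.28 against 8.44. The list mean was 4.31 on knockout array 1, 4.66 on knockout array 2, 4.92 on knockout array 3 and 5.42 on knockout array 4, against 4.96 to 5.74 on the wildtype arrays. Without knockout array 1 the median was -0.20 and the camera adjusted p 0.0846. Melanocyte markers were higher, with a median of 0.37, a camera adjusted p of 0.00582 and an adjusted p of 0.801 with an estimated correlation. The list mean was 3.29 on wildtype array 5 and between 4.09 and 4.24 on the other wildtype arrays, a range that also held knockout arrays 1 and 2, at 4.16 and 4.09. It was 4.36 on knockout array 3 and 4.76 on knockout array 4. Without wildtype array 5 the median was 0.23 and the camera adjusted p 0.0621, and without knockout array 4 the median was 0.22. Smooth muscle markers were higher, with a median of 0.54, a camera adjusted p of 0.0382 and an adjusted p of 0.801 with an estimated correlation. Their mean was 5.55 on knockout array 4 and between 3.25 and 3.70 on the other arrays, and without knockout array 4 the median was 0.16. None of the 12 melanocyte and 8 smooth muscle markers passed in limma, and 3 and 0 had an unadjusted p under 0.05. When adjusted over the list alone, 1 and 0 were higher. Adipocyte markers had a median of -1.25 and a camera adjusted p of 0.0781, with Adipoq at 3.37 ± 0.82 (SD, n = 4) against 6.43 ± 2.43 (SD, n = 5) and a list mean of 7.38 on wildtype array 3. On wildtype array 1 the adipocyte list mean was 4.39, within the range of 4.37 to 4.85 on the knockout arrays. In the sebocyte list 1 of 7 members fell, Far2, also 1 when adjusted over the list alone, with a camera adjusted p of 0.385. Fibroblast markers had a median of 0.37 and a camera adjusted p of 0.246. Their list mean was 7.93 on knockout array 4, where smooth muscle markers also stood high, and between 4.71 and 6.70 on the other arrays. Without knockout array 3 their median was 0.90 and the camera adjusted p 0.00562. Langerhans cell and macrophage markers had a median of -0.07 and a camera adjusted p of 0.776, with a list mean of 4.17 on wildtype array 5, 6.58 on wildtype array 4 and between 5.30 and 5.87 on the other arrays. Without wildtype array 5 their median was -0.35 and the camera adjusted p 0.00361. The camera adjusted p was 0.651 for T cells, 0.568 for mast cells and for neutrophils, and 0.638 for endothelium. It was 0.651 for skeletal muscle, 0.599 for erythroid cells and for Merkel cells, and 0.385 for Schwann cells and nerve.

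In all, 11 of 38 lists passed with camera's preset correlation of 0.01, 8 higher and 3 lower. With an estimated correlation 0 passed in camera and 2 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, gave 2. The number was 7 without knockout array 1 and 7 without wildtype array 4. It was 16 with the Xist covariate, 7 higher and 9 lower, and 13 both with the replicate block and without wildtype array 5, each with 7 higher and 6 lower. The last 2 fits give the same differences, since replicate number 5 is in wildtype only, so they are not separate checks. With the Xist covariate the melanocyte and smooth muscle lists did not pass, at camera adjusted p values of 0.273 and 0.291, and sterol synthesis, with a median of 0.50, passed as higher. The lists that were lower past the threshold with that covariate and not without it were Langerhans cells, with a median of -1.15, skeletal muscle, -1.50, adipocytes, -1.55, late cornified envelope, -0.71, sebocytes, -0.38, and the cell cycle, -0.18. That covariate sets knockout mainly against wildtype array 4, the only wildtype array with high Xist. Its skeletal muscle list mean was 6.39, against 3.85 to 5.63 on the other arrays. Its Langerhans cell list mean was 6.58, against 4.17 to 5.87, so these 2 medians rest largely on 1 array. Besides the hair follicle and melanocyte lists, the acylceramide list did not pass without knockout array 1, at a camera adjusted p of 0.0899, nor did the EGF receptor ligands without knockout array 1, at 0.133, or wildtype array 4, at 0.0596. Basal keratinocytes did not pass without knockout array 2, knockout array 3 or wildtype array 4, at 0.0611, 0.0653 and 0.0741. Smooth muscle did not pass without wildtype array 2, wildtype array 3 or knockout array 4, at 0.0694, 0.0552 and 0.337. Epidermal proteases did not pass without knockout array 1 or 3 or wildtype array 4 or 5, at 0.146, 0.0790, 0.105 and 0.102. The unfolded protein response did not pass without knockout array 1 or 2 or wildtype array 1, 2 or 4, at 0.137, 0.268, 0.05003, 0.0750 and 0.153. Other lists passed with 1 array left out. The late cornified envelope list did so without knockout array 1 or wildtype array 5, at 0.0308 and 0.000247, and the adipocyte list without wildtype array 1 or 5, at 0.00782 and 0.0420. Sterol synthesis did so without wildtype array 1 or 3 or knockout array 3 or 4, at 0.0470, 0.00597, 0.00193 and 0.00406. Stress keratins did so without wildtype array 3 or knockout array 3, at 0.0204 and 0.0120, and hypoxia and glycolysis without wildtype array 5, at 0.000144, in addition to fibroblasts and Langerhans cells.

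Genes that neighbour Alox12b were called about as often as others. Within 5 Mb of Alox12b in the GRCm38.p6 annotation 2 of 169 genes passed, or 1.18%, against 223 of 17863 elsewhere, or 1.25% (Fisher's exact test, 2-sided, p = 1). C1qbp fell by 0.70 and Zkscan6 rose by 0.63. Without the less specific probe sets neither passed, with limma adjusted p values of 0.0528 and 0.248, and with the mean of a gene's probe sets Zkscan6 did not, at 0.0630. In the epidermal differentiation complex, the cluster of cornified envelope genes between S100a10 and S100a6, 4 of 42 genes passed, or 9.52%, against 1.23% of 17990 other genes (Fisher's exact test, 2-sided, p = 0.00182). The genes were Sprr2h, Sprr2d, Sprr2k and Lce3c, all higher, while 19 of the 42 differences were positive. The only probe sets of Sprr2h and Lce3c were of the less specific kind, so the fit without these left both genes out. The share was 4.76% without knockout array 1 (Fisher's exact test, p = 0.110), 2.38% without knockout array 2 (exact p = 0.135), 4.76% with median centring (exact p = 0.0553) and 5.88% without the less specific probe sets (exact p = 0.0616).

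The arrays separated by genotype on the first principal component of the 2000 most variable genes, which held 43.2% of the variance. The knockout mean minus the wildtype mean was -35.4, and the 2-sided exact permutation test over 126 splits gave p = 0.00794, the smallest it can give. Wildtype array 5 lay at 43.25 and the other wildtype arrays between 7.71 and 10.01. The second component held 18.2% of the variance and the exact permutation p was 0.841. Knockout arrays 1 and 2 had a correlation across genes of 0.994 and lay apart from knockout arrays 3 and 4 on this component. Their correlations with knockout arrays 3 and 4 were 0.974 to 0.977, and with wildtype arrays 1 to 4 they were 0.980 to 0.986. Across all genes these 2 arrays were thus closer to most wildtype arrays than to the other knockout arrays. The upper quartile of the arrays was 5.11 ± 0.08 (SD, n = 4) in knockout and 5.24 ± 0.07 (SD, n = 5) in wildtype (exact permutation test, 2-sided, p = 0.0159). It was 5.21 and 5.15 on knockout arrays 1 and 2 and 5.04 and 5.03 on knockout arrays 3 and 4. Wildtype arrays 1 to 4 read 5.19 to 5.22 and wildtype array 5 read 5.37, so the shift was not shared by all knockout arrays. The exact permutation p was 0.0952 with median centring, 0.0571 without any one of wildtype arrays 2, 3, 4 and 5, and 0.114 without wildtype arrays 3 and 5. Array medians differed by 0.04 (exact permutation p = 0.294).

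**Figure D3:**
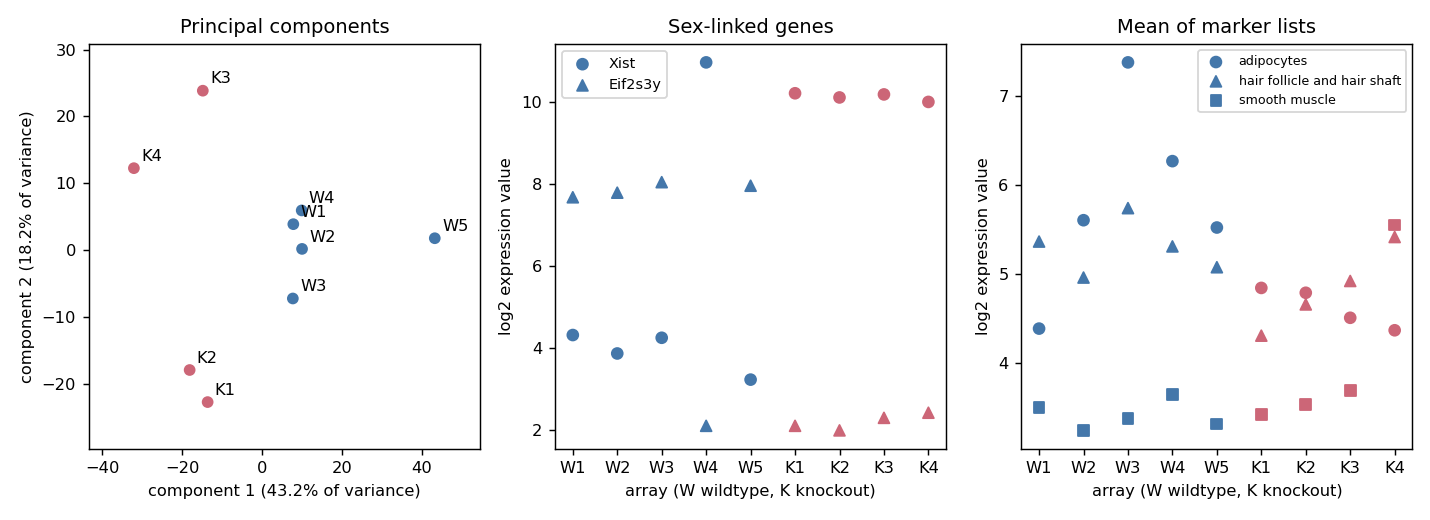
Principal components, log2 values of Xist and Eif2s3y, and mean log2 values of adipocyte, hair follicle and smooth muscle markers for each array, with wildtype in blue and knockout in red. Wildtype array 4 has Xist at 10.95, as high as the knockout arrays, and wildtype array 5 lies at 43.25 on the first component.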

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

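Arrays far from the rest of their group were looked for among 95 named genes and 4 array measures, in 198 groups of values. The gap to the nearest array exceeded Dixon's critical value in 25, where chance gives about 1 in 20, or 9.9. Of the 25, 13 were in wildtype array 5.

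Wildtype array 5 lay apart on the first principal component, at 43.25, and had the highest upper quartile of its group, at 5.37. It had the lowest wildtype values of Hbegf (4.32), Phlda1 (5.33), Atf3 (3.57), Cldn4 (9.46) and Pmel (3.95). It had the highest of Rsrp1 (10.53), Zfp799 (6.07), Zfp160 (5.97), Trp63 (8.65), Hk2 (8.26) and Ankrd37 (7.78). Both directions are those that widen the knockout difference for the called genes among these. Those genes were called and most were named for groups that do not overlap, which favours that direction. Among the genes not called, Cldn4, Pmel and Trp63 also went that way, while Hk2 and Ankrd37 went the other way.

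Wildtype array 4 stood out in Xist (10.95) and Eif2s3y (2.11), the female pattern that the knockout arrays also show. Wildtype array 3 stood out in Tnfaip3 (5.13) and Lpin1 (6.88), and wildtype array 2 in Hmgb2 (8.52) and Acta2 (4.42). Knockout array 4 stood out in Acta2 (9.19), Neu2 (6.21) and Kit (3.07), knockout array 3 in Ccn1 (5.96) and Fabp4 (5.78), and knockout array 2 in Cd2 (2.46).

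Probe sets that name no gene or several genes were left out of the gene comparison. Of 10092 such probe sets 109 passed the limma threshold, 15 higher and 94 lower in knockout.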

How the results depend on the processing

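The settings that left out wildtype arrays 3 and 5 together, or X and Y genes, were chosen after the data were seen. The cause of the changes below was not tested. The count of called genes, 226, was 45 at an adjusted p under 0.01 and 3232 at an unadjusted p under 0.05. It was 1644 with array weights, which ran from 0.31 for knockout array 4 to 3.37 for knockout array 2, and 1454 with a residual principal component, 712 higher and 932 lower in the first and 326 and 1128 in the second. The residual component leaves every difference as it was and lowers only the spread, so its higher count is no separate evidence. The count of called genes was 9 with the Xist level as covariate and 145 without wildtype arrays 3 and 5. Leaving out 1 array gave 62 to 281 genes. The count with at least 2-fold differences was 83 with the mean of a gene's probe sets (46 higher, 37 lower), 193 with each probe set on its own, 336 with array weights (188 higher, 148 lower), 254 with a residual component (84 higher, 170 lower) and 9 with Xist, and 57 to 148 with 1 array left out. Of 34 called named genes, quantile normalization kept 32, the Xist covariate 4 and the removal of knockout array 2 kept 15, and none turned direction in any setting run. Lists past the threshold numbered 0 with an estimated correlation, 2 by fry, 16 with the Xist covariate (7 higher, 9 lower) and 7 to 13 with 1 array left out. The share called in the epidermal differentiation complex was 5.88% without less specific probe sets, 4.76% with median centring and 2.38% to 16.7% with 1 array left out. The upper quartile difference of -0.13 was -0.18 with median centring, -0.099 without wildtype arrays 3 and 5 and -0.17 to -0.10 with 1 array left out, and its exact permutation p was 0.0952 with median centring and 0.0571 without wildtype array 2, 3, 4 or 5. The skeletal muscle list turned from a median of 0.02 to -1.50 with the Xist covariate. That fit rests mainly on wildtype array 4, which had the highest mean of this list. Same-numbered arrays had correlations of deviations of -0.21, -0.10, -0.21 and 0.18, which give no sign of pairing by number but cannot exclude it. With the replicate number as a block 119 genes passed, 84 of them among the 226, and 21 of the 34 called named genes were kept. The block also takes wildtype array 5 out of the comparison, and leaving out that array without a block gave 281 genes. A covariate for RNA quality from control probe sets was not run, since the table used here holds none, nor were alternatives for linear values. Signal near the background limits what dim genes can show.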

Other observations

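Tests of sex, of wildtype array 5 and of carried-over fat were chosen after the results were seen, as were all gene names in the next paragraph. The other tests were set beforehand, but requiring each median to pass its bound by more than its bootstrap interval over genes was added afterwards, as were the 20-gene Wnt list and the choice to judge sex and wildtype array 5 on unseen genes alone.

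Several genes outside the fixed lists are given as values only, with no test of what they share. Relb and Nfkb2, which encode NF-kB subunits, rose by 1.33 and 1.02, the adhesion molecule gene Icam1 by 1.08, Tnip1 by 0.88 and Irak3 by 1.67. Immediate early genes not looked at before also stood high. Of 35, 8 rose, 30 had a positive difference and the median was 0.53, above 100% of 10000 expression-matched random lists, with a camera p of 1.75e-10 and a p of 0.00559 with an estimated correlation. Dusp1 rose by 1.66, Fos by 1.37, Jun by 1.27 and Ier2 by 1.24. The 35 genes were listed after other immediate early genes had been seen high on the same arrays. The random lists were matched on level alone, not on how genes move together, so the high median is no separate support. Zinc finger genes with Zfp symbols were lower more often than others, 9 of 336, or 2.68%, against 0.694% (Fisher's exact test, p = 0.000823), a grouping seen first and then tested on the same data.

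The higher immediate early genes were weighed first against 1 deviating array, and without wildtype array 5 the median of the 35 unseen genes was 0.50, with a bootstrap interval from 0.33 to 0.97, above the point of 0.062 that 2.5% of matched lists exceed, which argues against that array alone. With the Xist covariate that median was 0.39 against 0.53, and of the 9 genes that then passed 6 were immediate early genes, Arc at 3.09 against 2.65, Nr4a1 at 3.37 against 3.09, Junb at 2.51 against 2.18, Zfp36 at 2.25 against 2.09, Btg2 at 2.15 against 2.01 and the unseen Dusp1 at 2.15 against 1.66. Sex as the cause predicts smaller differences there, but 5 of the 6 were chosen for being high and the fit rests on the 1 of 5 wildtype arrays that shares the knockout sex pattern, so sex and genotype cannot be told apart for the group. Longer or hotter handling predicts heat shock genes above 0.3, and their median over 22 genes was 0.065, at percentile 97.49. The rule set beforehand, a median under 0.15 and below the point that 2.5% of matched lists exceed, was narrowly met and would have argued against handling, but the bootstrap interval ran from -0.051 to 0.32, so handling stays open, as does the biological candidate, a response to the missing barrier lipid, which was not tested.

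A further look at sex used wildtype array 4, chosen after its pattern was seen. In a fit without it 89 genes passed, and on a scale from the other wildtype arrays at 0 to knockout at 1 its median position was 0.076, nearer to wildtype for 84 of 89. It is 1 array, so this excludes nothing about sex. The 226 genes all kept their sign with the Xist covariate, but wildtype array 4 helped to select them.

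The lower hair follicle markers, with a median of -0.50, were weighed against 3 explanations. A compressed range of the knockout arrays predicts a median like that of expression-matched lists, whose 2.5% point was -0.21. The bootstrap interval of -0.62 to -0.30 lay below it, which by the rule would argue against a compressed range. That interval takes genes as independent, though their estimated correlation was 0.47, and holds no spread between arrays. Without knockout array 1 the median was -0.20, outside the interval, so a compressed range stays open. Without wildtype array 5 the median was -0.62, which argues against that array alone. Lower Wnt signalling, the biological candidate, predicts lower Wnt targets, but 18 unseen targets had a median of 0.11, with an interval of 0.022 to 0.18, above the 25% point of matched lists at 0.012, which by the rule set beforehand would exclude it. That list left out Axin2 and Apcdd1, which fell by 1.76 and 1.57, although a second, dimmer probe set of Axin2 differed by 0.16, and with both put back the median of 20 was 0.10, at percentile 86.6, with an interval of -0.0064 to 0.17 that just reached the 25% point of 0.00030, and 14 of 20 positive, so lower Wnt signalling stays open.

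The adipocyte markers had a median of -1.25 but did not pass as a list (camera adjusted p of 0.0781), and 0 of 6 passed in limma. The lower median was weighed against 2 explanations. Expression-matched lists had a 2.5% point of -0.35, and by the rule set beforehand this would argue against a compressed range, but the bootstrap interval of the 6 markers ran from -2.41 to 0.053, so it stays open. Fat carried over with some wildtype sheets predicts markers that move together within groups. Their mean pairwise correlation was 0.41, above 99.8% of matched lists but under the 0.5 needed, so carried-over fat stays open. Adipoq reached 9.46 on wildtype array 3 and Fabp4 10.58. Of the 6 markers, Fabp4 is also on the fatty acid oxidation list, and no biological explanation was tested.

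Other splits of the arrays into 4 and 5 were tried, 100 drawn with the real one. For called genes, 1 of 100 gave as many as the real 226, the real split itself, and the highest other gave 9. This argues against a chance division of the arrays as the source of the count. Most other splits put knockout and wildtype arrays in one group, which widens the spread, and the splits cannot tell genotype from sex. For at least 2-fold differences 1 of 100 gave as many as the real 126, and the highest other gave 9. For gene lists 52 of 100 gave as many as the real 11, and the highest other gave 22, so chance cannot be excluded for the number of lists past the preset-correlation threshold.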
